A study of Homo sapiens with 4 samples.

How the data were processed

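RNA from 4 cell cultures was measured on Affymetrix Human Genome U133 Plus 2.0 arrays, a platform that reads polyadenylated transcripts near their 3' ends with short oligonucleotide probe sets. The cultures were H929 and U266 myeloma cells, each with 500 nM pristimerin in 0.1% DMSO or with 0.1% DMSO alone for 4 h, and each of the 4 groups holds 1 array. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was hybridised.

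The deposited values are probe-set intensity on a linear scale. Per the series' design text and the submitters' processing notes, the authors summarised them with the PLIER algorithm plus an offset of 16 in Affymetrix Expression Console, with the software version not given in the sources used here. The smallest deposited intensity is exactly 16 on every array, which shows that the offset is already in the values, and the values are neither logarithms nor ratios to DMSO. The planned transformation of linear values was log2(value + 16). Because the 16 was found to be present already, log2 of the deposited intensity was used, and the addition of a further 16 became an alternative. The offset shrinks the fold changes of dim genes, so folds below are on the scale of signal plus 16. The authors also made detection calls with the MAS5 algorithm, per the design text, and these were not used here.

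The table holds 54675 probe sets. The platform annotation gave 1 gene symbol for 41097 of them, several for 1801 and no listed symbol for 11777, of which 62 are control probe sets. Symbols were updated by Entrez ID with a RefSeq gene table (assembly GRCh38.p14), which matched 41043 of the probe sets with 1 symbol, while 54 kept the annotation's symbol. The array's own genome build is not given in the sources used here, so no coordinates are reported. A probe set was kept if the highest of its 4 values was at or above the median of all values on all arrays, 24.73 signal units, in place of detection calls. This left 35247 probe sets, 27906 of them with 1 gene symbol. Each gene took the value of its kept 1-symbol probe set with the highest mean, which gave 15282 genes, 7087 of them with more than 1 kept probe set. Genes measured only by probe sets with several symbols are not named. HSPA1A, HSPA1B and HSPA1L are among these.

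The response common to both lines was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend in the prior variance), with cell line as a block. Adjusted p-values are Benjamini-Hochberg values over the 15282 genes, two-sided, with a threshold of 0.05. The pairing follows from the cell line of origin, and line accounted for 89.4% of the variance between arrays. The fit leaves 1 residual degree of freedom per gene, and eBayes adds 9.35 from the spread shared by genes of like brightness. Gene lists written before the data were examined were tested on the same fit with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over 24 lists, and again with the correlation estimated per list. Within a line, between the responses of the lines and between the lines in DMSO there is 1 array per group, so genes past a fold threshold were counted without a test. List medians within a line were set against 10000 random lists of the same size matched on mean expression. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the figures; tables were read and joined with data.table (version 1.17.8) in R.

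The test was tried on simulated data built for the common response, with 200 changed genes among 15282 in each of 20 simulations. It recovered 90.4% of genes changed 2-fold and 99.4% of genes changed 4-fold, and 16.1% of its calls were false, above the nominal 5%. With the prior variance known the false share was 5.02%, and without the trend it was 2.58%. Camera called 20 of 20 moved lists and 0 of 460 unmoved lists at the preset correlation, but 0 of 20 moved lists with the estimated correlation. The simulated genes varied independently of each other, so the 0 of 460 does not show that camera's p-values hold for lists of correlated genes. The estimated correlation in the data, 0.84 for ATF4 targets and 0.53 for interferon genes, does not measure such correlation. With 1 residual degree of freedom it reflects only how the members split between the lines. The higher ratio was in H929 for 24 of 25 ATF4 targets and 20 of 23 interferon genes.

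The genes named across both lines are the 15 largest rises and 15 largest falls in mean log2 fold change among genes past the test and at least 1.5-fold the same way in each line. Only 3 falls qualified, so 3 further genes at least 1.5-fold lower in each line are given as values. Also named are up to 4 members of each list by size, the 8 genes with the largest difference in response each way, the 8 with the largest DMSO difference each way, and CCND1, CCND2, NSD2, FGFR3, MYC and IL6. Genes named outside this rule are said to be so. The lists cover heat shock proteins, NRF2 targets, ATF4 targets, endoplasmic reticulum chaperones, proteasome subunits, ubiquitin and autophagy adaptors, NF-kappaB targets, immediate early genes, metallothioneins, p53 targets, apoptosis regulators, G1 and S phase genes, G2 and M phase genes, plasma cell genes, ribosomal proteins, cholesterol synthesis, interferon response, histones, housekeeping genes and markers of 5 other kinds of cell.

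Alternatives fixed before the data were examined were no filter or a stricter filter on dim probe sets, centring or quantile normalization of the arrays, a further offset of 16, the mean of a gene's probe sets, exclusion of probe sets open to cross-hybridisation, no variance trend, no cell-line block, other thresholds, each probe set tested alone, and other forms of camera. Loess normalization within each line's pair of arrays was chosen after seeing the data. Array data carry no read depth, and precision is limited by the number of arrays.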

Results

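Gene expression was profiled in H929 and U266, 2 human multiple myeloma cell lines, after 4 h with 500 nM pristimerin or with the DMSO vehicle. Pristimerin is a quinone methide triterpenoid isolated from plants of the Celastraceae family. H929 carries a translocation that places FGFR3 and NSD2 under immunoglobulin enhancers, and U266 is an IgE-secreting line that expresses cyclin D1. The dose was near 2 times the IC50 and the harvest preceded visible loss of viability, per the series' design text, which sought a signature shared by both lines. Each group was a single array. The cell line is therefore the only replicate, and no value within a line has a replicate check. P-values, SEs and intervals of the common response temper each gene's gap between these 2 lines with the spread of genes of like brightness. Those genes give 9.35 degrees of freedom and the gene itself 1. An SE can therefore understate the gap: DDIT4 had log2 ratios of 1.85 in H929 and 1.16 in U266, beside an SE of 0.13.

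Median signal was 24.8 units on the H929 DMSO, H929 pristimerin and U266 DMSO arrays and 24.6 on the U266 pristimerin array, on a scale whose floor is 16. Pearson's r of log2 signal over all probe sets was 0.976 between the H929 arrays, 0.985 between the U266 arrays and 0.893 between the DMSO arrays of the lines. The 3'/5' signal ratio of ACTB, a measure of RNA integrity, was 1.25 with DMSO and 1.42 with pristimerin in H929, and 1.93 and 2.17 in U266. The 9 spiked-in bacterial control probe sets had a median 1.28-fold higher signal on the pristimerin array of H929, where 9 of 9 were higher, and 1.04-fold in U266, where 5 of 9 were higher.

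The first comparison asked which transcripts pristimerin moved in both lines. Of the fixed lists, 13 of 24 heat shock genes and 9 of 25 ATF4 targets rose with pristimerin. Both list calls were lost in camera with an estimated correlation (adjusted p = 0.693 and 0.704 with an estimated correlation). That form called 0 of 20 moved lists in the simulations, so here and below it cannot decide for or against a list. HSPA6, a strictly stress-inducible member of the HSP70 family, went from 31.45 to 2185 signal units in H929 and from 30.54 to 2878 in U266, which is 69.5-fold and 94.2-fold (mean log2 change 6.34, 95% interval 6.10 to 6.58, limma adjusted p = 3.03e-10). Its other kept probe set had a mean log2 change of 2.37, and the mean of both was 4.35, so the size depends on the probe set and on DMSO signals near the floor. BAG3, a co-chaperone of HSP70, rose 2.88-fold in H929 and 5.19-fold in U266, and DNAJB1, an HSP40 co-chaperone, rose 2.92-fold and 4.05-fold. In all, 42 of 15282 genes passed the test, 39 higher and 3 lower with pristimerin, a split that depended on scaling (102 higher and 63 lower after quantile normalization). In the simulations 16.1% of this test's calls were false, against 2.58% without the variance trend. In the data the form without the trend called HSPA6 alone, so the calls of all other genes rest on the trend.

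Among the 15 largest rises beside these chaperones were HSPH1 (mean log2 change 1.33 ± 0.12 limma SE, n = 2 lines, adjusted p = 0.000709) and SERPINH1, the collagen chaperone of the endoplasmic reticulum (1.19 ± 0.13). Stress-response genes of the ATF4 pathway made up another part. DDIT4, an inhibitor of mTORC1, rose by 1.50 ± 0.13 (adjusted p = 0.000709), CHAC1, a glutathione-degrading enzyme, by 1.50 ± 0.19, and the secreted factor STC2 by 1.45 ± 0.18. The transcription factor ATF3 rose by 1.18 ± 0.20, CTH, an enzyme of cysteine synthesis, by 1.17 ± 0.16, and SESN2, a stress-induced regulator of mTORC1, by 1.11 ± 0.14. SLC7A11, the cystine transporter, rose by 1.26 ± 0.19 and HMOX1, the haem-degrading enzyme, by 1.36 ± 0.23. With no filter the calls of CHAC1 (adjusted p = 0.075), STC2 (0.0637), INHBE (0.183), SLC7A11 (0.148), CTH (0.0799), SESN2 (0.055), ATF3 (0.211) and HMOX1 (0.225) were lost, and those of HSPA6, BAG3, DNAJB1, HSPH1, SERPINH1, DDIT4 and DEDD2 held. The call of ATF3, whose probe sets ranged from 0.07 to 1.18, was lost with the mean of its probe sets (0.64, adjusted p = 0.134), and that of HMOX1 with a further 16 added (adjusted p = 0.12) and without cross-hybridising probe sets (adjusted p = 0.0506). The probe set of HMOX1 is not of the cross-hybridising kind, and its change stayed at 1.36 without them, so only the adjusted p moved. INHBE, an inhibin beta subunit, rose by 1.37 ± 0.22, and DEDD2, a death effector domain protein, by 1.19 ± 0.11. HMOX1 was 4.00-fold higher in U266 (117.8 to 471.7 units) against 1.65-fold in H929 (29.75 to 48.97), whereas CHAC1 was 4.12-fold higher in H929 against 1.95-fold in U266.

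TRABD2A fell by 1.24 on the log2 scale (SE 0.17, adjusted p = 0.0132), with 18.88 and 19.59 signal units left on the pristimerin arrays. C10orf90 fell by 0.99 and GALNTL6 fell by 0.88, both with an adjusted p of 0.0423. Their sizes are uncertain too: with pristimerin C10orf90 had 25.96 units in H929 and 16.82 in U266, and GALNTL6 had 33.45 and 24.87. With a further 16 added the changes were -0.64 and -0.63. With the mean of a gene's probe sets the calls of TRABD2A (-0.71, adjusted p = 0.116; its other probe set -0.18) and C10orf90 (-0.47, adjusted p = 0.352) were lost, and those of C10orf90 and GALNTL6 were lost with a stricter filter (adjusted p = 0.0641 and 0.0695). All 3 were lost with no filter (adjusted p = 0.055, 0.145 and 0.183), and GALNTL6 with a further 16 added (0.0716). For C10orf90 a further kept probe set moved the opposite way, as for IRF2BP2 and MALAT1 among the genes that rose, which are named here after their values were seen. Past 1.5-fold lower in each line but not past the test were ATP12A (mean log2 change -1.04, adjusted p = 0.0763), GLDN (-0.70, 0.0839) and LILRB5 (-0.64, 0.36), none of them above 56.1 signal units.

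At an unadjusted p under 0.05 the counts were 1135 higher and 330 lower, and with the design text's limits of 1.5-fold and a false discovery rate of 0.25 they were 69 and 12. The count of 42 depended on how the spread was modelled and the arrays scaled: HSPA6 alone passed without the variance trend and 0 genes without the cell-line block (smallest adjusted p = 0.253, 69 genes at an unadjusted p under 0.05), 13 passed with no filter, 165 after quantile normalization, 110 after loess within pairs (75 higher, 35 lower), and 440 probe sets when each was tested alone.

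**Figure D1:**
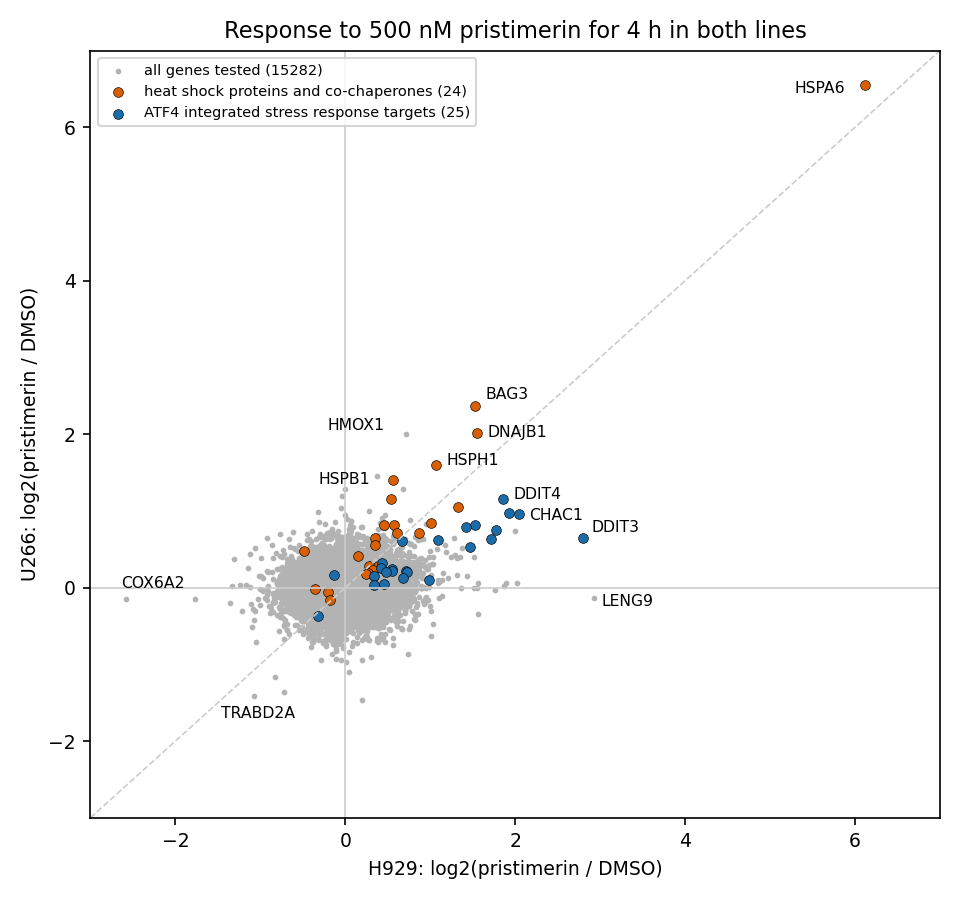
Each point is a gene, at its log2 ratio of pristimerin to DMSO in H929 (horizontal) and in U266 (vertical), with the 24 heat shock genes in orange, the 25 ATF4 targets in blue and the diagonal dashed. HSPA6 lies apart at 6.12 and 6.56, most ATF4 targets lie below the diagonal and 16 of 24 heat shock genes lie above it.

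Gene groups fixed in advance were then compared. Of 24 measured heat shock proteins and co-chaperones 13 rose, none fell and 11 did not pass, and 19 rose when p was adjusted over the list alone. Besides HSPA6, BAG3, DNAJB1 and HSPH1, the members that rose included HSP90AA1, the inducible cytosolic HSP90 (mean log2 change 0.93, adjusted p = 4.1e-06), and the mitochondrial chaperonin HSPD1 (0.50) with its partner HSPE1 (0.63), all 3 picked for naming after their values were seen. With no filter the calls of HSPD1 and HSPE1 were lost (adjusted p = 0.055 each). The list passed camera (adjusted p = 1.34e-31), but not with an estimated correlation (adjusted p = 0.693 with an estimated correlation). The median member was 1.34-fold higher in H929 and 1.61-fold in U266.

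Of 25 ATF4 targets, genes induced when phosphorylation of eIF2 alpha increases ATF4 translation, 9 rose and 16 did not pass, and 22 rose when adjusted over the list alone (camera adjusted p = 4.62e-27, adjusted p = 0.704 with an estimated correlation). DDIT4, CHAC1 and STC2 led those that passed. DDIT3, which encodes the transcription factor CHOP, had a mean log2 change of 1.72 and did not pass the test (adjusted p = 0.11). Its signal went from 25.95 units, close to the filter, to 180.6 in H929 and from 123.8 to 193.3 in U266, so the size of that mean is uncertain. The median member was 1.64-fold higher in H929 and 1.19-fold in U266.

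Among 25 NRF2 targets, genes of the antioxidant response, HMOX1 and SLC7A11 rose, 23 did not pass, and 5 rose when adjusted over the list alone. SLC7A11 also belongs to the ATF4 list. The glutamate-cysteine ligase genes GCLM (mean log2 change 0.43, adjusted p = 0.19) and GCLC (0.41, adjusted p = 0.291) did not pass. The list's camera adjusted p was 7.76e-05 (adjusted p = 0.693 with an estimated correlation). Of 9 metallothionein and metal response genes, MT2A (0.82, adjusted p = 0.0134) and the zinc exporter SLC30A1 (0.89, adjusted p = 0.00457) rose, and 4 rose when adjusted over the list alone. MT2A is read by a single kept probe set, of the cross-hybridising kind, so without these it is not measured, and with no filter its call was lost (adjusted p = 0.0585). MT1H (0.53) and MT1X (0.40) did not pass (camera adjusted p = 0.000122, adjusted p = 0.693 with an estimated correlation).

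Of 23 endoplasmic reticulum chaperone and folding genes only ERN1, the IRE1 alpha sensor of unfolded proteins, rose (mean log2 change 0.79, adjusted p = 0.0328), and it was also the only member past the test when adjusted over the list alone. Its 3 kept probe sets ranged from 0.17 to 0.79, and the call was lost with their mean (0.40, adjusted p = 0.217) and with no filter (0.148). SEC24D, DNAJB9 and EDEM1 had values of 0.76, 0.59 and 0.43 in H929 and 0.01, 0.02 and 0.17 in U266. The list passed camera (adjusted p = 8.57e-05, adjusted p = 0.704 with an estimated correlation). Of 17 ubiquitin and autophagy adaptors, ZFAND2A, an arsenite-inducible proteasome-associated protein, rose (0.98, adjusted p = 0.0184) and 3 rose when adjusted over the list alone. With no filter the call of ZFAND2A was lost (adjusted p = 0.0923). GABARAPL1 (0.39), ZFAND5 (0.36) and WIPI1 (0.29) did not pass (camera adjusted p = 0.000142, adjusted p = 0.704 with an estimated correlation).

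None of 29 proteasome subunit genes passed the gene test, over all genes or over the list alone, while the list passed camera (adjusted p = 0.000142, adjusted p = 0.693 with an estimated correlation), with a median member 1.09-fold higher in H929 and 1.07-fold in U266. PSMC6 (0.26) and PSMD12 (0.25) had the largest mean log2 changes. The list's camera call was lost after quantile normalization (adjusted p = 0.393) and after loess (adjusted p = 0.142). Its median log2 ratios, 0.12 in H929 and 0.10 in U266, were 0.04 and 0.02 after quantile normalization and 0.04 in each line after loess. Of 27 cytoplasmic ribosomal protein genes none passed over all genes and 3 rose when adjusted over the list alone. Their median log2 ratios were 0.06 in H929 and 0.04 in U266, near those of all genes (0.06 and 0.02), with a camera adjusted p of 7.76e-05 (adjusted p = 0.693 with an estimated correlation) that was lost after quantile normalization (adjusted p = 0.0948).

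SESN2 and GADD45A rose among 17 p53 targets, and 4 rose when adjusted over the list alone. SESN2 is also an ATF4 target in the lists used, and GADD45A an immediate early gene. PMAIP1, the BH3-only protein NOXA, had log2 ratios of 1.37 in H929 and 0.51 in U266 (adjusted p = 0.0824), and CDKN1A had 0.57 and 0.14. The list's camera adjusted p was 0.00806 (adjusted p = 0.704 with an estimated correlation, 0.0591 with a stricter filter and 0.141 with rank-based camera). Of 15 housekeeping genes none passed over all genes, and 1 rose and 4 fell when adjusted over the list alone. TUBB had the most negative mean log2 change, -0.22 (adjusted p = 0.0915). Camera placed the list below other genes (adjusted p = 0.039, adjusted p = 0.704 with an estimated correlation), a call lost with no filter (adjusted p = 0.124), after centring (0.0636), without cross-hybridising probe sets (0.97) and with rank-based camera (0.285), with medians of -0.04 in H929 and 0.01 in U266, the latter below 0 after quantile and loess normalization.

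NF-kappaB targets did not pass as a list (28 measured, none past the gene test over all genes or over the list alone, camera adjusted p = 0.635). NFKBIZ, TNFAIP3 and NFKBIA, feedback inhibitors or regulators of the pathway, had log2 ratios of 0.91, 0.82 and 0.84 in H929 and 0.13, 0.08 and -0.21 in U266, and a further kept probe set of NFKBIA showed -27.5% of its difference between the lines. Of 26 immediate early genes, JUN (mean log2 change 0.96, adjusted p = 0.0398) and GADD45A (0.72, adjusted p = 0.041) rose, with 8 higher and 2 lower when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.217). The call of JUN was lost with the mean of its probe sets (adjusted p = 0.0797), without cross-hybridising probe sets (0.101), with a stricter filter (0.0512) and with no filter (0.185), and that of GADD45A with no filter (0.154). DUSP1 (0.59) and IER5 (0.53) did not pass.

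No gene passed over all genes in the lists of 25 plasma cell and myeloma genes (camera adjusted p = 0.98), 19 regulators of apoptosis (0.908), 26 G1 and S phase genes (0.484), 27 G2 and M phase genes (0.33), 17 cholesterol synthesis genes (0.372), 23 interferon response genes (0.484) or 14 histone genes (0.95). Adjusted over the list alone, 2 plasma cell genes rose and 2 fell, 1 apoptosis regulator rose and none passed in the other 5 lists. XBP1, the plasma cell transcription factor, had log2 ratios of -0.51 in H929 and -0.06 in U266. Markers of other cell types did not pass either: mature B cells (7 measured, camera adjusted p = 0.878), T and NK cells (6, 0.113), myeloid cells (6, 0.635), erythroid cells and platelets (3, 0.372), and fibroblasts and epithelium (8, 0.217). No member of these 5 lists passed over the list alone. In the cell cycle G1 and S, cholesterol, interferon, histone and myeloid lists, the median over both lines was above 0 while camera, which compares with all other genes, placed the list lower.

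In total 10 of 24 lists passed camera, 9 higher and 1 lower, and 0 did with an estimated correlation (smallest unadjusted p = 0.0778, for heat shock genes). The latter form also called 0 of 20 moved lists in the simulations, so its result does not decide. Without the cell-line block 3 lists passed, the heat shock, ATF4 and metallothionein lists. A camera call does not by itself show a shift beyond genes of like brightness in each line. Against matched random lists, ribosomal protein medians stood at percentile 60.2 in H929 and 34.1 in U266. Endoplasmic reticulum genes stood at 100 and 11.4, whereas the heat shock and ATF4 lists stood at 100 in each line.

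**Figure D2:**
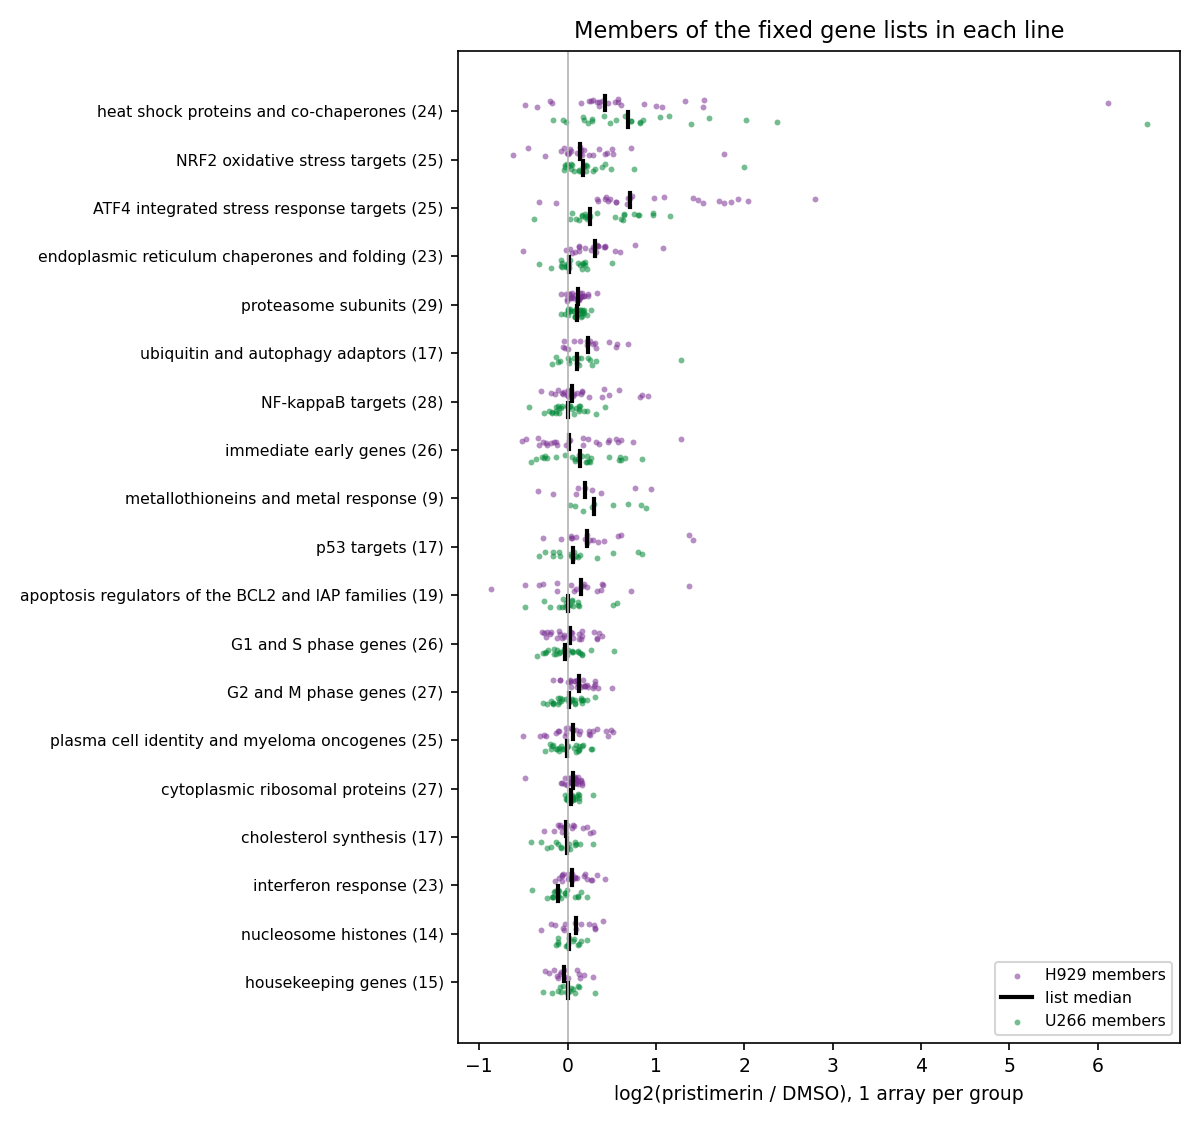
Each point is a measured member of a gene list, at its log2 ratio of pristimerin to DMSO in H929 (purple) or U266 (green), 1 array per group, with list sizes in brackets and black bars at the list medians. The medians of the heat shock list are 0.42 in H929 and 0.68 in U266, and those of the ATF4 list are 0.71 and 0.26.

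Within H929, ATF4 targets and then heat shock genes had the highest medians among the 24 fixed lists. The median ATF4 target was 1.64-fold higher with pristimerin, above all 10000 random lists of like brightness (percentile 100), and 15 of 25 members were at least 1.5-fold higher. CHAC1 was 4.12-fold higher, STC2 3.81-fold and DDIT4 3.61-fold. INHBE, which is in none of the fixed lists, was 4.00-fold higher. DDIT3 was 6.96-fold higher from a DMSO signal of 25.95 units, close to the filter of 24.73 and not shown to lie above background, so the size of its ratio is uncertain. The heat shock list had a median of 1.34-fold (percentile 100) with 8 members past 1.5-fold. The endoplasmic reticulum list had a median of 1.24-fold (percentile 100), with ERN1 2.11-fold, SEC24D 1.70-fold and DNAJB9 1.51-fold higher. Over all genes 479 were at least 1.5-fold higher and 292 at least 1.5-fold lower, against 58 and 22 at 2-fold, on a pair of arrays whose bacterial spikes differed 1.28-fold. Much of the 1.5-fold count came from dim genes, the lower ones above all: it was 134 higher and 38 lower with a further 16 added to each signal and 287 and 72 with a stricter filter. After quantile normalization it was 375 and 332. Of the genes with further kept probe sets, 39 of 290 past 1.5-fold were backed by the others, and 2 of the 69 lower ones. Those others are dimmer on average, because the brightest was chosen, and the offset can shrink their ratios below 1.5-fold.

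Within U266, heat shock genes had the highest median among the 24 fixed lists, 1.61-fold (percentile 100), with 13 of 24 members at least 1.5-fold higher. Among its measured members, after HSPA6 came BAG3 at 5.19-fold, DNAJB1 at 4.05-fold and HSPH1 at 3.03-fold. The list members HSPA1A, HSPA1B and HSPA1L have no 1-symbol probe set and are not ranked. Probe sets 202581_at and 200800_s_at, which list several symbols, were 13.0-fold and 11.9-fold higher, above BAG3. HMOX1, in the NRF2 list, was 4.00-fold higher, and that list's median of 1.13-fold stood at percentile 99.98. The median ATF4 target was 1.19-fold higher (percentile 100), with 10 of 25 members past 1.5-fold. Endoplasmic reticulum genes had a median of 1.01-fold (percentile 11.4), which was below 1 after quantile and loess normalization, and none was past 1.5-fold. Counts over all genes were 146 higher and 109 lower at 1.5-fold, and 16 and 5 at 2-fold. They were 44 higher and 10 lower at 1.5-fold with a further 16 added, and 74 and 34 with a stricter filter, and other probe sets backed 15 of 71 genes that had them, none of the 29 lower ones.

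The series' design text derived a shared signature from the overlap of both lines. HSPA6, BAG3, DNAJB1, DDIT4, CHAC1 and STC2 were all at least 1.5-fold higher in each line. At this threshold 33 genes were higher in both lines, against 4.58 if the lines were independent, and 6 were lower in both, against 2.08. Opposite directions were found for 2 genes higher in H929 and lower in U266 (3.42 if independent) and for 4 genes lower in H929 and higher in U266 (2.79). Of the genes past the limma test, 26 were at least 1.5-fold higher and 3 at least 1.5-fold lower in each line. Across genes, which are not independent replicates, Pearson's r of the log2 ratios of the lines was 0.203 and Spearman's rho 0.164, and without the genes past the test they were 0.137 and 0.158. The lines share no control array. The overlap of 39 genes was 25 with a further 16 added and 8 at 2-fold.

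**Figure D3:**
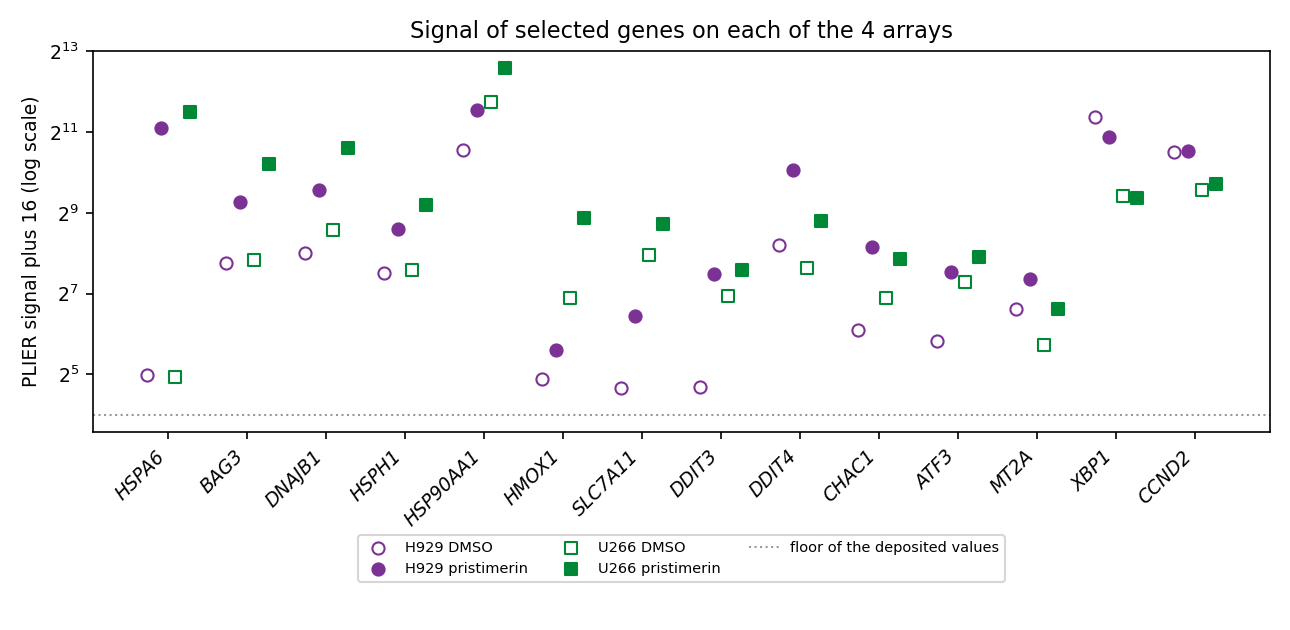
Signal plus the deposited offset of 16, on a log2-spaced axis, for 14 genes on each of the 4 arrays, with DMSO as open and pristimerin as filled symbols, H929 in purple and U266 in green. HSPA6 goes from near the floor to 2185 and 2878 units, while DDIT3 starts at 25.95 units in H929 and at 123.8 in U266.

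The responses of the lines were then set against each other, without a test. Of 25 ATF4 targets 24 had the higher log2 ratio in H929, with a median difference of 0.49, above all matched random lists (percentile 100). Of 24 heat shock genes 16 had the higher ratio in U266, with a median difference of -0.22 (H929 minus U266, percentile 0, 95% bootstrap interval over list members -0.36 to 0.00338). DDIT3 had ratios of 2.80 in H929 and 0.64 in U266, and BAG3 had 1.53 and 2.38. A difference of at least 2-fold was found for 133 genes, 76 with the higher ratio in H929 and 57 in U266, a split without a stable direction (64 and 60 after quantile normalization, 44 and 47 with the mean of a gene's probe sets, 44 and 18 with a stricter filter).

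The 8 largest differences toward H929 were LENG9, DDIT3, SLC25A17, MUC4, GLP1R, STRIT1, ANKEF1 and SKI. LENG9 went from 26.8 to 203.5 signal units in H929 and from 86.23 to 78.86 in U266. SLC25A17, a peroxisomal transporter, went from 16.04 units, the floor, to 65.02 in H929 and from 93.76 to 97.85 in U266. SKI, a repressor of SMAD signalling, went from 51.79 to 18.7 in U266 and from 55.47 to 63.76 in H929. Toward U266 they were COX6A2, TRIO, PARD3-DT, LINC00174, XCR1, CLDN5, PLAU and BOK. COX6A2, a cytochrome c oxidase subunit, went from 96.17 to 16.01 units in H929 and from 92.16 to 83.47 in U266. PARD3-DT reached 78.44 units at most, and LINC00174, XCR1, CLDN5, PLAU and BOK at most 34.84. Among the 44 genes of the 133 with further kept probe sets, those other probe sets showed a median of 1.59% of the difference (95% bootstrap interval -6.86 to 6.87). They are dimmer on average than the chosen one, and the offset shrinks dim ratios. The count of 133 was 18 with a further 16 added, 62 with a stricter filter and 1274 at a 1.5-fold difference.

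Last, the lines were compared in DMSO, where they differ by origin. H929 had higher signal of AMPD1, a muscle-type AMP deaminase (2017 against 26.01 units), FGFR3 (722.4 against 17.47), the integrin subunit ITGB7 (3147 against 110.7) and GPRC5D, a plasma cell surface receptor (606.6 against 19.47). NES, UBE2C, CDK6 and ITM2A were the other large differences that way, and 5 of the 7 kept probe sets of CDK6 moved opposite to the chosen one with pristimerin. U266 had higher immunoglobulin transcripts IGH (5308 against 26.55) and IGLL5 (3719 against 22.96), CD74, the invariant chain of MHC class II (1219 against 16.01), and CD52 (1667 against 16.01). QPCT, TRBC1, TMPRSS3 and the interferon-induced IFI27 completed the 8. CCND1 was 815.5 units in U266 and 24.07 in H929, CCND2 was 752.5 and 1457, and NSD2 was 141 and 415.7. MYC was 253.9 units in H929 and 29.09 in U266, and IL6 was 25.34 and 54.04. None of these genes passed the test for pristimerin. In all, 840 genes were at least 2-fold higher in H929 and 1127 in U266. That total of 1967 was 1292 with a further 16 added and 406 at 4-fold.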

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

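The tests chosen only after their result was seen are those of a single gain factor between the lines, the reading of the spread of unexpressed probe sets, the percentile set for the correlation of ATF4 targets with their DMSO level, the interval on the counts backed by other probe sets, and loess normalization.

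XCR1 and PLAU moved opposite ways in the lines, at least 1.5-fold each: the log2 difference in response, H929 minus U266, was -1.57 for XCR1 (-0.92 and 0.64) and -1.47 for PLAU (-0.77 and 0.70). The differences were not tested, and neither gene was above 33.6 signal units. Among probe sets that the comparisons of named genes leave out, 200800_s_at, which lists 3 gene symbols, was 3.99 higher on the log2 scale with pristimerin in H929 and 3.58 in U266, and 202581_at, which lists 2 symbols, was 3.95 and 3.70 higher. Probe set 1564798_at, with no listed gene, was 4.78 higher in H929 (23.78 to 652.1 units) and -0.05 in U266 (570.3 to 552.1). Probe set 237064_x_at, also without a listed gene, was 2.03 higher in U266 (94.67 to 387.7) and -0.63 in H929.

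More genes passed 1.5-fold in H929 (771) than in U266 (255). A noisier pair of H929 arrays may account for part of the excess. Division of the H929 ratios by 1.11, the ratio of the spreads of unexpressed probe sets, left 510 genes. Division by 1.13 to 1.39, the ratios of the spreads between probe sets of a gene at like brightness, left 349. There the H929 share of both counts (95% interval 53.7% to 61.8%) includes the 60% that stands for a 1.5-fold excess, but lies above an equal share. An offset that varies with intensity is argued against: after loess 709 genes passed in H929 and 247 in U266. Erratic values of single probe sets stay open too: of the genes with further kept probe sets, 39 of 290 in H929 (37 of the 39 higher) and 15 of 71 in U266 were backed by the others at 1.5-fold. The 95% binomial interval of the H929 share, 58.4% to 83.5%, reaches below 60% but also lies above an equal share. Both intervals treat genes as independent, so a stronger response of H929 is not established.

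Of 25 ATF4 targets 24 had the larger ratio in H929, and of 24 heat shock genes 16 had it in U266. Compression of dim genes by the offset of 16 is argued against for ATF4 targets by its direction. Their median DMSO signal was 90.58 units in H929 and 227.5 in U266, so compression would shrink the H929 ratios more. The 17 targets of at least 64 units in DMSO of both lines differed by a median of 0.47 (95% interval 0.31 to 0.62), 17 of 17 the same way. On these arrays the 2 lists did not share a single gain factor. The 2.78 times larger median log2 ratio of ATF4 targets in H929 (difference 0.49, 0.31 to 0.72) would give heat shock genes a difference of 1.22 (0.13 to 2.06), and theirs was -0.22 (-0.36 to 0.00338). The intervals in this paragraph resample list members, which are not independent, on 1 array per group. They hold no error between arrays, so the question stays open for the lines themselves. A higher DMSO level in U266 that leaves less room to rise could also contribute: the targets' DMSO signal was a median 1.54-fold higher in U266, and over the targets this difference correlated with the difference in response (Spearman's rho 0.49), but at percentile 94.8 of random lists, where the shared DMSO arrays alone gave a median rho of 0.17. A difference between the lines in sensitivity to the drug remains a further hypothesis, untested.

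Genes whose responses differed 2-fold between the lines rarely had that difference in their other probe sets, which showed a median of 1.59% of it (95% interval -6.86 to 6.87, 44 genes). An erratic estimate of the chosen probe set on an array may therefore account for much of this class, although other probe sets can also read other transcripts of a gene. For genes called across both lines the share was 73.7% of the mean change. The 2 shares are unlike: the first genes were picked, untested, for an extreme difference in 1 probe set, which by itself lowers the share in the others. The called genes passed a test on the mean of both lines. In 17 of the 133 genes a single array stood at least 2-fold from the rest, 9 times the H929 DMSO array. For fixed-list genes 1.5-fold apart the share was 30.2% (1.02 to 58.8, 20 genes), which leaves the question open for them too. Of these, SLC7A11 had 24.7% and ATF3 29.9%.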

How the results depend on the processing

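Loess within each pair of arrays was chosen only after the data were seen, and the other alternatives were fixed before the data were examined. The 42 genes called across both lines became 13 with no filter on dim probe sets, 165 after quantile normalization, 110 after loess, 1 without the variance trend, 0 without the replicate block (limma, smallest adjusted p = 0.253, 69 genes at an unadjusted p under 0.05), 81 at a false discovery rate of 0.25 with 1.5-fold, and 440 probe sets when each was tested alone. All 42 were among the calls after quantile and loess normalization, and all 13 left with no filter were among the 42. The share of calls that were higher went from 92.9% to 61.8% after quantile normalization and 68.2% after loess. A stricter filter, centring, a further 16, the mean of a gene's probe sets and exclusion of cross-hybridising probe sets gave 35 to 47 genes. Of 10 lists called by camera, 0 held with an estimated correlation (0 lists at an unadjusted p under 0.05) and 3 without the replicate block, while 8 to 11 lists passed under the other settings. The estimated correlation also called 0 of 20 moved lists in the simulations, so it cannot decide. Genes past 1.5-fold in H929 (771) became 359 with a stricter filter, 172 with a further 16 and 80 at 2-fold, and those in U266 (255) became 108, 54 and 21. The 39 genes past 1.5-fold the same way in both lines became 25 with a further 16 and 8 at 2-fold. The 133 genes with a response 2-fold apart became 62 with a stricter filter, 18 with a further 16 and 1274 at 1.5-fold, and the 1967 genes apart in DMSO became 1292 with a further 16 and 406 at 4-fold. Thresholds act on these counts by construction, filters on the counts past a fold likewise, and a further 16 by shrinking the ratios of dim genes. For the normalizations, and for the drop from 42 to 13 calls with no filter, the cause was not tested. With no filter BAG3 kept its mean log2 change of 1.95 while its limma adjusted p went from 0.000366 to 0.00735. No named gene of the common response and no called list changed sign in a setting with 1 value per gene, but C10orf90 (0.04) and GLDN (0.05) have a kept probe set above 0. Of 21 such genes, 17 lost the call without the trend, 18 without the block and 11 with no filter, while ATP12A and GLDN passed after quantile and loess normalization, and ATP12A with the mean of a gene's probe sets. Leaving out a line leaves no residual degree of freedom, so the values are then those of the other line, with no test. Signal limits the lower end: 24.73 units, the filter, lies close to the floor of 16.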

Other observations

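The percentile tests of tubulins and aminoacyl-tRNA synthetases were chosen after results were seen, as were the gene groups themselves. For tubulins the genes already seen were left out, and for synthetases the members of the fixed lists.

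Of 17 cytoplasmic aminoacyl-tRNA synthetase genes, the enzymes that attach amino acids to tRNA, 16 were higher in H929 (median 1.26-fold) and 14 in U266 (median 1.08-fold, percentile 92.3 of matched random lists). Their median log2 ratios, 0.33 in H929 and 0.10 in U266, were 0.23 and 0.03 after quantile normalization and 0.24 and 0.05 after loess. GARS1 was 1.56-fold higher in H929 and 1.15-fold in U266, YARS1 1.44-fold and 1.16-fold, and TARS1 1.42-fold and 1.11-fold. None passed the limma test across both lines. KARS1 was lower in H929, at 0.919-fold. Of 10 amino acid transporter genes, 9 were higher in each line. Their medians were 1.35-fold in H929 and 1.18-fold in U266. The 7 outside the fixed lists had medians of 1.29-fold and 1.18-fold. SLC7A11 passed the test and belongs to the ATF4 list, as do SLC7A5 and SLC3A2. SLC38A2, a transporter of small neutral amino acids, was 2.36-fold higher in H929 and 1.32-fold in U266 (adjusted p = 0.0553).

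On the DMSO arrays, cultures held 4 h in vehicle, 20 of 25 ATF4 targets were higher in U266, by a median of 1.54-fold, at percentile 99.99 of matched random lists, and by 1.44-fold after quantile normalization. With pristimerin the median ratio of U266 to H929 was 0.991 and 12 of 25 were higher in U266. DDIT3 had 123.8 units in U266 DMSO and 25.95 in H929 DMSO, then 193.3 and 180.6 with pristimerin.

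A hypothesis that the synthetases were higher in H929 as a group, beyond what chance among genes of like brightness gives, was tested on the 15 that are in none of the fixed lists. Their median of 1.23-fold stood at percentile 100 in H929, and that in U266 at percentile 92.5. The former argues against a chance draw of genes of like brightness on that pair of arrays. It holds no error between arrays, and the bacterial spikes of the H929 pair differed 1.28-fold. The difference between the lines was not tested, and genes of a common programme are not independent.

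A second hypothesis, that tubulin transcripts are lower with pristimerin in both lines, came from TUBB, TUBA1B and TUBA1C. All 14 tubulins together had medians 1.06-fold lower in H929 and 1.08-fold lower in U266, at percentiles 0.11 and 0.08, but this includes the genes that prompted it. The 11 others stood at percentile 2.11 in H929 and 14.4 in U266, within the range of chance in U266, and only 5 of 11 were lower in both lines. At the main scaling the hypothesis was therefore not borne out beyond the genes first seen. There the median log2 ratios of the 11 were -0.07 in H929 and -0.02 in U266. They were -0.14 and -0.10 after quantile normalization and -0.15 and -0.08 after loess, where no percentile was computed.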
